A study of Homo sapiens with 2 samples.

How the data were processed

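Ribosome profiling libraries of 2 HEK293T cultures were compared, 1 from cells co-transfected with a fluorescent reporter plasmid and 1 from cells without it. The groups were taken from the sample titles, which the labels' protocols explain. Per the labels' protocols, both cultures were grown in dishes of 15 cm and received the plasmid for the TetRS synthetase and its tRNA. They were collected after 30 h of expression, following 1 min in medium with 0.1 mg/mL cycloheximide, and the libraries were sequenced as single-end reads of 50 nt.

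The count table, as deposited, held whole-number counts for 61554 rows, of which 2 were plasmid sequences, the mCherry-T2A-EGFP reporter and TetRS. TopHat2 2.0.12 and HTSeq 0.9.1 are listed, with no role or order, per the submitters' processing notes. The handling of strand and of reads with several matches is not given in the sources used here. Those notes list the builds GRCh37 and hg19. The coordinates in the files were nevertheless those of GRCh38, since 19063 of the 19065 coding symbols found in the RefSeq GRCh38.p14 gene table overlapped their locus there. Coordinates below are printed as the files give them.

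A second table held RPKM values deposited by the authors for the same rows, with a scaling that the file headers do not describe. Set against the counts, each RPKM value equalled the count divided by the listed gene length and by 1 library size, in the usual units. That size was 2873483 with the reporter and 2762965 without it, or 1.14 and 0.877 times the summed counts. No gene deviated from it by more than a relative 1e-9.

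The summed counts were 2519301 with the reporter and 3151403 without it. Counts were scaled by edgeR 4.0.16 with the TMM method over all rows in R 4.3.3. The main set was the 1060 protein-coding genes with a summed count of at least 100 over both libraries, out of 19994 in the table. Values are log2 ratios of scaled counts, with the reporter over without it. Each has an exact Clopper-Pearson interval at 95%, which covers counting error only, because each group had 1 library. The interval takes every read as independent. Reads copied by PCR without molecular identifiers are not independent molecules, so it may be too narrow even for counting error. A gene was counted as higher or lower where its ratio was at least 2-fold and the interval excluded 0. With 1 library per group no test across replicates exists, so no p-value is given. Every difference below is one between these 2 libraries, without a replicate check, and not one between the conditions.

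For fixed gene lists, the median log2 ratio of the measured members was taken minus the median of the main set. It was placed among 10000 random lists of the same size, matched on 20 bins of expression. A list with at least 6 measured members was said to stand apart at a percentile of at most 2.5 or at least 97.5. Chance gives this to 1 list in 20 only where members vary independently, and genes of 1 pathway may vary together. For lists with fewer measured members, and for cell type markers, counts were pooled over all members with a count and set against all coding counts. The 23 pathway lists, the 6 marker lists, the thresholds and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the highest and the 12 with the lowest ratio, ranked by the interval bound nearest to 0. It also took the 5 most counted genes of each library, the highest and lowest measured member of each list, and 9 genes of stress responses, seryl-tRNA charging and housekeeping. Loci without a symbol were skipped, and 1 gene that the rule takes is not reported here.

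The steps were tested on simulated counts for the 1060 genes, with 50 genes at each fold size. The 2-fold rule found 48% of genes simulated at 2-fold, 98% at 3-fold and 6% at 1.5-fold, and none of the 860 unchanged genes. Those simulated genes varied by counting error only. The result therefore does not give the share of false calls in the real libraries, which spread more widely. Of 100 lists of 20 genes shifted by 0.4, 90 stood apart, as did 6 of 100 unshifted lists. Their genes were drawn at random, so this does not cover lists whose members vary together. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these steps.

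The alternatives were DESeq2 1.42.0 size factors, total counts, other count minimums and fold thresholds, the deposited RPKM values with 0.1 added, all RNA classes, thinning of the deeper library, and an assumed variation between libraries. Further alternatives were added after the data were seen and are named with their results. A planned comparison with the density of TCG codons was not run, because coding sequences were not used here. Without a matched RNA library, a difference in footprint counts can come from the amount of an mRNA or from its translation.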

Results

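Ribosome profiling sequences the RNA fragments that ribosomes protect from nuclease, so that the counts of a gene follow the number of ribosomes on its mRNA. The libraries came from HEK293T cells, a line derived from human embryonic kidney that takes up plasmids readily. Both cultures expressed TetRS, in the labels a variant of the chimeric pyrrolysyl-tRNA synthetase. The same plasmid carried U6-driven cassettes, listed as 12, for a tRNA with the anticodon CGA, the complement of the serine codon TCG. The compound that the labels call TetBu was present in both. Only 1 culture also received the reporter, in which mCherry and EGFP are joined by a T2A peptide and 1 position of EGFP is encoded by TCG. The series title places the work in the use of rare codons for noncanonical amino acids. As both libraries held the tRNA, the comparison asks what differed with the reporter plasmid present, not what the tRNA does. The amount of the tRNA was not measured, and TetRS from the same plasmid had fewer counts with the reporter, as given below. A difference in the dose of that plasmid cannot be told apart from the reporter. Each group had 1 library, with 2519301 counts with the reporter and 3151403 without it.

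Most counts in both libraries came from noncoding RNA. Mitochondrial rRNA took 44.8% with the reporter (exact interval 44.8 to 44.9%) and 45.4% without it (45.3 to 45.4%). Nearly all of it was MT-RNR1, the small mitochondrial rRNA, at 41.1% and 42.7%. Annotated miRNA genes took 12.5% (12.4 to 12.5%) against 30.4% (30.4 to 30.5%). Protein-coding genes took 13.7% (13.7 to 13.8%) against 9.77% (9.73 to 9.80%), or 346240 and 307768 counts. The share of mitochondrial tRNA was 6.77% against 4.63%, and that of snoRNA, the guide RNAs of rRNA modification, was 2.18% against 1.40%. Genes of the rRNA biotype had 20 and 19 counts. The 10 most counted genes of each library held 72.0% and 78.5% of its counts. Among coding genes, 14017 had a count and only 50 reached a summed count of 1000.

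**Figure D1:**
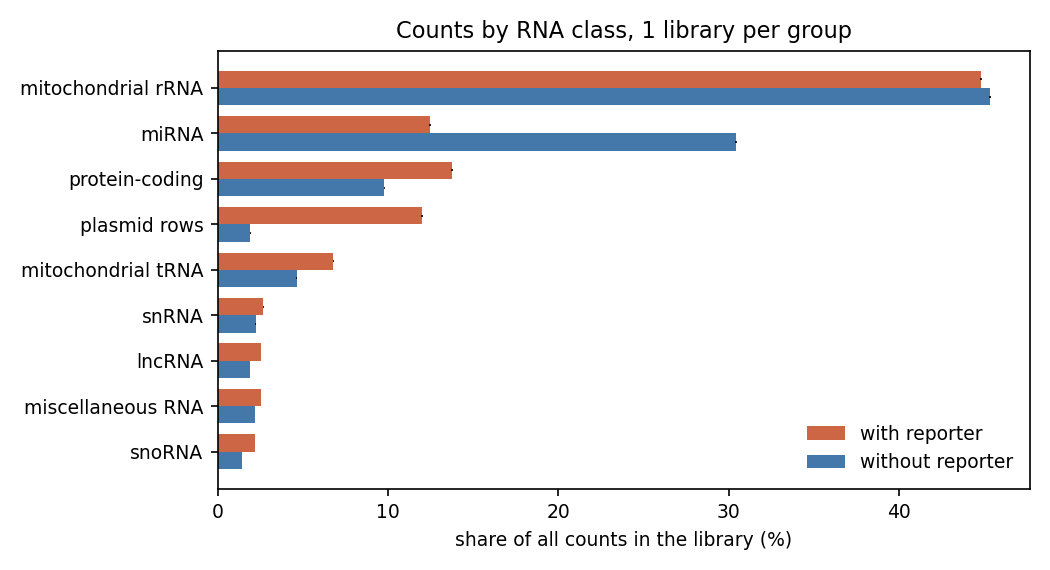
Share of all counts (x axis, %) in each RNA class for the library with the reporter and the library without it, with exact 95% intervals that are narrower than the bar ends. The miRNA share was 12.5% with the reporter and 30.4% without it, and the plasmid rows held 11.99% and 1.91%.

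The reporter was the second most counted row with the reporter plasmid, at 271843 counts or 10.8% of the library. The other library held 399 counts of it, or 0.0127% (0.0114 to 0.0140%). The scaled ratio was 622-fold (564 to 688), a log2 ratio of 9.28, in the direction the titles give. The source of the 399 counts is not settled, and if they came from outside this culture the fold is a lower bound. Among coding and plasmid counts together, the reporter held 41.9% in the first library. TetRS, encoded on the plasmid that both cultures received, had 30286 counts with the reporter and 59723 without it. Its log2 ratio was -1.11 (-1.13 to -1.09), and -1.22 relative to the median coding gene. Of the 1060 coding genes measured, 6 had a lower ratio, and none of the 50 with at least 1000 counts did. Scaling by total counts brought the log2 ratio of TetRS to -0.66.

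Across the 1060 coding genes the libraries ranked genes alike, with a Spearman correlation of 0.76 across genes, which are not independent replicates. The median log2 ratio was 0.11, and scaling by total counts moved it by 0.46, so list values below are relative to it. Unless stated, values of single genes are not set against this median or against all coding counts. A gene and its list therefore do not share the same zero. The rule counted 30 genes as at least 2-fold higher with the reporter and 6 as lower. Counting error alone gave a mean of 0.425 and 0.005 such genes in 200 simulations. Under total counts 190 genes were higher and none was lower, so the split of calls rests on the scaling. The ratios spread with an SD of 0.48 among genes with 100 to 200 counts, where counting error gave 0.26. Among the 50 genes with 1000 counts or more it was 0.42 against 0.066. With no replicate, this spread could not be divided into an effect of the reporter and differences between cultures or libraries.

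**Figure D2:**
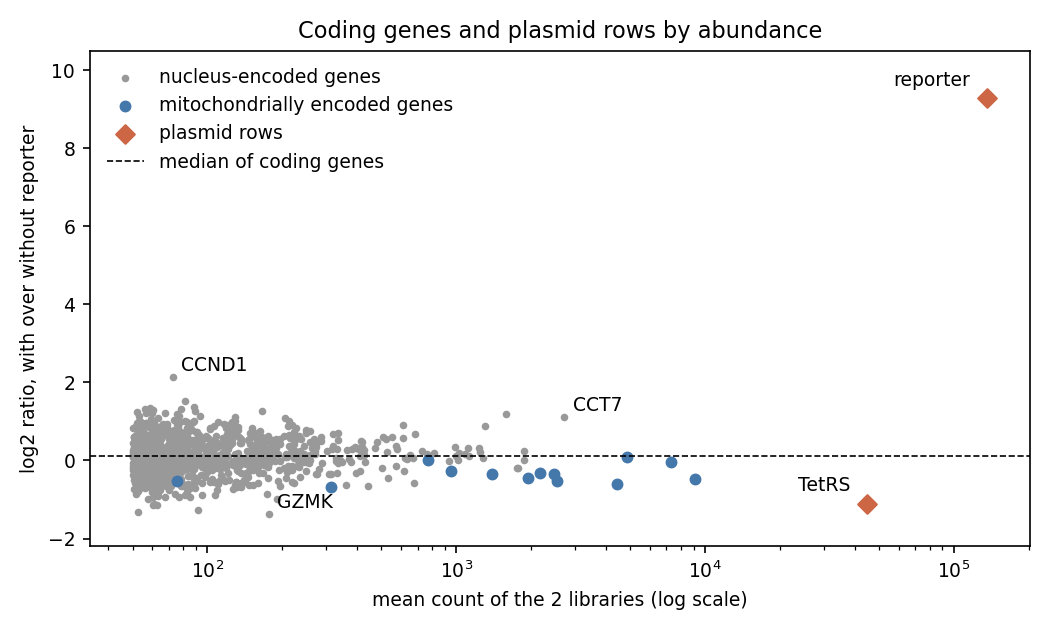
Log2 ratio of scaled counts, with over without the reporter (y axis), against the mean count of the 2 libraries (x axis, log scale). Each point is 1 of 1060 coding genes or a plasmid row. The reporter lies at 9.28 and TetRS at -1.11, and the dashed line marks the coding median of 0.11.

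CCND1, which encodes cyclin D1, had the highest ratio (chromosome 11, 69641156 to 69654474), with 120 counts against 25 and a log2 ratio of 2.13 (1.5 to 2.8). It was the only gene at least 3-fold higher. CCT7, a subunit of the cytosolic chaperonin, was the most counted gene among those higher, with 3822 counts against 1615 (1.11, 1.03 to 1.20). RCC1, the exchange factor of the GTPase Ran, was at 1.18 (1.07 to 1.29), but its locus holds the snoRNA gene SNORA73B. COX6C, a subunit of cytochrome c oxidase, was at 1.52, and the prefoldin subunit PFDN4 was at 1.09. NUDC, a regulator of dynein, was at 1.26, BCCIP at 1.38, FHL1 at 1.31, ARF5 at 1.26 and STOML2 at 1.36. BDH2 was among the 12 highest by interval bound, at 0.91, below the 2-fold threshold.

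The lowest ratio was that of GZMK, which encodes a granzyme of cytotoxic lymphocytes (chromosome 5, 55024256 to 55034570). It had 105 counts with the reporter and 249 without it (-1.38, -1.72 to -1.04). Its deposited RPKM without the reporter was 57.5, above the 35.5 of GAPDH. Leukocyte markers together had only 5 counts against 20, so whether these reads came from GZMK mRNA is uncertain. Among those markers, CORO1A had 1 count against 14 and LCP1 0 against 6, while CD14 had 3 against 0 and LYZ 1 against 0. The other 5 genes counted as lower were STT3A, a catalytic subunit of the oligosaccharyltransferase, at -1.28, KLHL15 at -1.32, SAP130 at -1.15, the DNA repair gene XRCC2 at -1.13 and the mitochondrial fusion gene MFN2 at -1.11. None of these 6 passed under total counts. RPS26, SMC4, ATP5MJ, RPL10, GCN1 and MT-CYB completed the 12 lowest without reaching 2-fold, at -0.98, -0.86, -0.95, -0.67, -0.88 and -0.61. SMC4 holds the gene of MIR16-2, and RPL10 that of SNORA70. RPS26 and RPL10 have many processed pseudogenes, so their counts are uncertain.

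Counts of respiratory chain genes differed by the genome that encodes them. The mitochondrially encoded proteins are made by mitochondrial ribosomes, which cycloheximide does not inhibit, so the 2 sets of counts are not fully alike. All 13 mitochondrially encoded genes lay below the coding median, with a relative median of -0.46 (-0.65 to -0.14, percentile 0.01). MT-ND2 was lowest at -0.69 (-0.92 to -0.46) and MT-ND4 highest at 0.09 (0.03 to 0.15), with 5235 counts against 4489. These genes held 10.4% of coding counts with the reporter and 13.2% without it. Nucleus-encoded genes of oxidative phosphorylation had a relative median of 0.36 (0.08 to 0.51, percentile 99.85), with 19 of 25 measured members above the coding median. COX6C and NDUFA1 were counted as higher, at 1.52 and 1.05, while NDUFS7 was lowest at -0.79. Among random lists drawn from all RNA classes, the mitochondrially encoded list was at percentile 8.065, and among genes with at least 1000 counts it was at 6.57. Relative to the coding median, MT-RNR1 was at -0.62, MT-RNR2 at -0.11 and the mitochondrial tRNA genes at -0.20 (-0.27 to 0.12). A difference in mitochondrial RNA in general was thus not separated from one in these messages.

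Chaperones of the cytosolic heat shock response were higher with the reporter as a list, with 12 of 13 measured members above the coding median. The relative median was 0.36 (0.22 to 0.76, percentile 98.98). HSPA1B was at 0.93 (0.42 to 1.45), the Hsp40 gene DNAJB1 at 0.87, HSP90AB1 at 0.60 and HSPA8 at 0.54. DNAJA1 was lowest at -0.09. None of the members reached the 2-fold rule. HSPA1B shares nearly all of its sequence with HSPA1A, which had 2 counts against 0, so the pair is uncertain. Without genes that hold a small RNA gene the list was at percentile 97.08, just short of standing apart.

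Replication-dependent histones had a relative median of 0.26 (-0.03 to 0.43, percentile 99.13), with 14 of 20 measured members above the coding median. H4C1 was counted as higher at 1.00 and H2AC13 was lowest at -0.54. Histone genes of 1 type are near-identical copies, so reads may be split among them by the counting. After a trend of ratio on gene length was removed, an alternative chosen after seeing the data, the relative median was 0.04 and the percentile 62.805. By the mean of its members the list was at percentile 96.61. Cell cycle genes had a relative median of -0.26 (-0.40 to 0.12, percentile 1.725), with 11 of 16 below the coding median. PCNA, the replication clamp, was at -0.72 (-1.10 to -0.35), but CCND1 belongs to the same list. By the mean of its members the list was at -0.10 and percentile 17.83. It also did not stand apart without genes that hold a small RNA gene (percentile 16.04) or among all RNA classes (percentile 4.0).

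Apart from the heat shock response, translation and stress lists did not stand apart. Cytosolic ribosomal proteins had a relative median of 0.06 over 67 genes, with RPL13A highest at 0.76 and RPS26 lowest. Initiation factors were at -0.04 over 21 genes, between EIF3K at 0.68 and EIF4G3 at -0.57. Elongation and termination factors were at -0.02 over 7 genes, between EEF1B2 at 0.70 and GSPT1 at -0.45. Cytosolic aminoacyl-tRNA synthetases were at 0.07 over 13 genes. EPRS1 was counted as higher at 1.21, TARS1 was at -0.41, and SARS1, which charges serine tRNAs, was at 0.46 (0.03 to 0.90). The 8 measured members of the list of ATF4 and its targets were at -0.07. SESN2 was counted as higher at 1.07, while ATF4 itself was at -0.44 (-0.76 to -0.13), or -0.56 relative to the coding median. Genes of the unfolded protein response were at 0.11 over 12 genes, with SSR1 at 0.74, XBP1 at -0.66 and the ER chaperone HSPA5 at 0.00 (-0.30 to 0.30). All 10 measured factors of ribosome collision and quality control lay below the coding median, from RACK1 at 0.11 to GCN1, yet their relative median of -0.15 was at percentile 17.8. DDIT3, ASNS and CDKN1A, markers of stress responses, had 4, 2 and 8 counts against 4, 1 and 6, so a difference was not detectable at this depth.

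The remaining lists with a percentile did not stand apart by their medians either. Targets of p53 were at 0.38 over 6 genes (percentile 95.6), from SESN2 down to PMAIP1 at 0.09. By the mean of its members this list stood apart as higher, at 0.40 and percentile 98.14. Proteasome subunits were at 0.18, between PSMB3 at 0.96 and PSMD2 at -0.43. Glycolysis was at -0.14, between GPI at 0.47 and PGK1 at -0.80. Nonsense-mediated decay was at -0.18, between EIF4A3 at 0.75 and UPF1 at -0.55. The tRNA and RNA polymerase III machinery was at -0.17, between POLR3D at 0.54 and GTF3C1 at -0.52. The housekeeping genes GAPDH and ACTB were at -0.05 (-0.31 to 0.21) and 0.08 (-0.23 to 0.38).

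**Figure D3:**
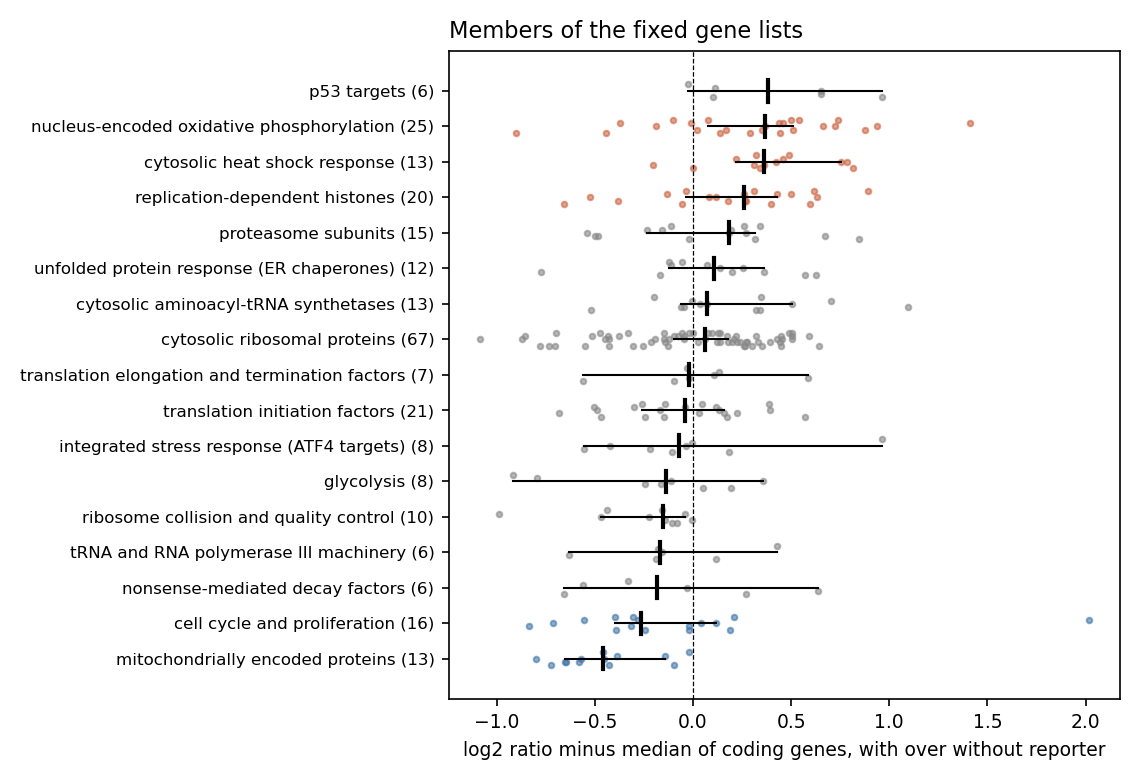
Log2 ratio of each measured member minus the coding median (x axis) for the 17 fixed lists with at least 6 measured members, whose number is in brackets. Thick ticks are medians and lines their 95% binomial intervals. Lists in orange stood apart as higher with the reporter and lists in blue as lower, with mitochondrially encoded genes at -0.46.

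Lists with fewer than 6 measured members were compared by their pooled counts. Selenoproteins had 964 counts against 581, a log2 ratio to all coding counts of 0.56 (0.41 to 0.71). The phospholipid peroxidase GPX4 was counted as higher at 1.00 (0.70 to 1.31), and SEPHS2 was at 0.22. Immediate early genes were at 0.20 (0.11 to 0.30), with MYC at 0.41 and JUN at 0.19. Interferon and innate immune genes were at -0.42 (-0.67 to -0.18), with 250 counts against 298, and ZC3HAV1 was at -0.51. At a minimum of 20 counts, the immediate early genes were at percentile 92.86 and the interferon and innate immune genes at 7.615, so neither list stood apart. Mitochondrial ribosomal proteins were at 0.01 (-0.09 to 0.12), with MRPS2 at 0.56 and MRPL18 at -0.27. Cholesterol biosynthesis was at -0.06 (-0.27 to 0.14), with SREBF2 at -0.02. Autophagy and lysosome genes were at 0.16 (-0.01 to 0.32), with BECN1 at -0.13.

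Markers of other cell types were sparse and differed between the libraries. Fibroblast and mesenchymal markers had 47 counts with the reporter and 77 without it, a log2 ratio to all coding counts of -0.88 (-1.44 to -0.34, percentile 2.26). COL1A2 and COL3A1 had 4 counts each against 21 and 19, while ACTA2 had 23 against 9. Leukocyte markers had 5 counts against 20 (-2.17, -3.94 to -0.71, percentile 1.995), with CORO1A and LCP1 lower and CD14 and LYZ, at few counts, not. Erythroid and serum markers had 0 counts against 16 (percentile 0.165), of which ALB made 13. Hepatocyte and keratinocyte markers had 92 counts against 49 (0.74, 0.22 to 1.27, percentile 94.5), mostly CDKN2A at 86 against 34. Without CDKN2A, chosen after seeing the data, the list had 6 against 15 (percentile 7.26, within the range of random lists), with the hepatocyte genes SERPINA1 at 0 against 8 and APOB at 1 against 4. Neuron-like genes that HEK293 cells express had 236 against 172 (0.29, -0.003 to 0.58), with NEFL at 0.98 and NEFM at 0.03. Embryonic kidney and adrenal genes had 55 against 80 (-0.71, -1.23 to -0.20, percentile 6).

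Annotated miRNA genes were lower with the reporter as a class. Over 97 genes the median relative to coding genes was -1.03 (-1.27 to -0.81), and 82 had an interval below the coding median against 5 above it. MIR148A was the second most counted gene without the reporter (chromosome 7, 25949919 to 25949986). It had 614704 counts there against 95417, a log2 ratio of -2.82 (-2.83 to -2.81). MIR182 was at -0.65 and MIR10B at -0.54, with 81986 and 46312 counts with the reporter. With MIR148A left out of both the miRNA counts and the total, an alternative chosen after seeing the data, the miRNA share was 9.01% against 13.6%. MT-RNR1 was at -0.51 and the large mitochondrial rRNA, MT-RNR2, at 0.01.

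**Figure D4:**
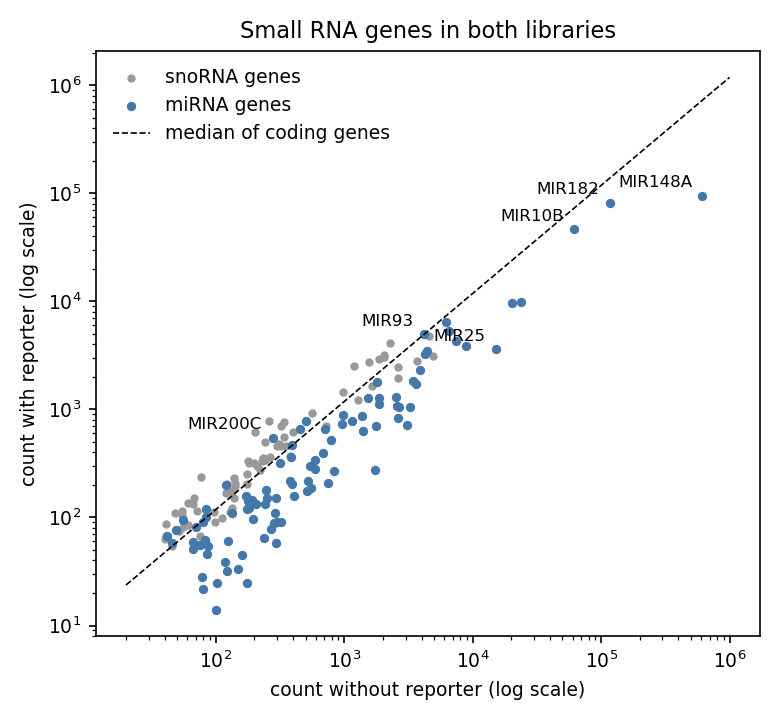
Counts with the reporter (y axis) against counts without it (x axis), both on log scales, for miRNA and snoRNA genes with a summed count of at least 100. The dashed line marks the median ratio of coding genes. Most of the 97 miRNA genes lie below it, with MIR148A at 95417 against 614704 counts.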

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

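The values of TetRS and of miRNA genes and most scalings were planned, but their use to weigh explanations in this part, and the tests of spread, were chosen after the result was seen. The library without the reporter plasmid held 399 counts of the reporter, where a count of 0 would allow up to 3, and it stands out as signal of a sequence that this culture did not receive. It came to 0.147% of the 271843 counts in the other library. Of 41 other genes with at least 3000 counts there, the lowest such percentage was 42.3%, for CCT7. Those genes belong to the line or to the plasmid that both cultures received, so the design itself gives them far higher percentages. The comparison does not bear on the source of the 399 counts. Carry-over between the libraries and sequence shared with the TetRS plasmid stay open as sources and were not tested, since reads and plasmid sequences were not used here.

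TetRS had 59723 counts without the reporter and 30286 with it, although both cultures received its plasmid. Depth taken up by the reporter would lower all genes alike, but TetRS lay at -1.22 relative to the median coding gene. The choice of scaling does not account for it either, since the highest log2 ratio under any scaling run was -0.66. A difference between dishes in transfection cannot be told apart from an effect of the reporter plasmid, because each group had 1 library. Competition between the plasmids for uptake, transcription or ribosomes is a hypothesis that was not tested.

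The miRNA genes lay at -1.03 relative to coding genes, so depth taken up by the reporter, which would leave that value near 0, cannot be the cause. The SD of their log2 ratios was 5.196 times their counting error. It was also 3.06 times for snoRNA, 4.79 times for mitochondrial tRNA and 2.04 times for coding genes. That ratio depends on depth, and the SD itself was 0.87 for miRNA genes. It was 0.52 for snRNA, 0.49 for snoRNA, 0.46 for coding genes and 0.28 for mitochondrial tRNA. A loss of short inserts by 1 common factor would not widen the spread, so it alone does not account for that of miRNA genes. Such a loss stays open as a part of the difference. MIR25 at -2.19, MIR93 at 0.13 and MIR106B at -1.46 start at 100093560, 100093768 and 100093993 of chromosome 7. A loss of short inserts that differs with their sequence and a difference in the amount of RNA outside ribosomes stay open. An effect of the reporter on miRNAs themselves was not tested.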

How the results depend on the processing

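The alternatives named as length trend, coding rows, plasmid rows, small RNA genes, mitochondrial genes and miRNA denominators were chosen after seeing the data. Of the values compared, 257 of the main ones were within their interval or within 1.5 times, and 28 were not. None changed sign among those called. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. The 2 results on TCG codons were not run. At a minimum of 1000 counts only 2 lists kept 6 members.

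The counts of 30 higher and 6 lower genes became 190 and 0 under total counts, 420 and 412 at a minimum of 20, 2 and 0 at a minimum of 1000, and 577 and 630 with no minimum. They were 156 and 66 at 1.5-fold and 1 and 0 at 3-fold. DESeq2 size factors gave 46 higher genes, among them all 30, and all RNA classes together gave 56 lower. These follow from which genes or folds are admitted and, for total counts and DESeq2, from a shift of the median by 0.46 and 0.08. TetRS was at -1.04 with DESeq2 and with the deposited RPKM values and at -0.66 under total counts, where the reporter was at 9.74. Ribosome collision factors were at -0.0035 with no minimum. Mitochondrially encoded genes were at -0.66 with the length trend removed, and the cause was not tested. The miRNA shares with and without the reporter were 14.2% and 31.02% without plasmid rows and 22.6% and 55.7% without mitochondrial rRNA, through the smaller total. They were 9.01% and 13.6% with MIR148A left out of both the miRNA counts and the total, and 8.67% and 10.9% with it left out of the miRNA counts only. The oxidative phosphorylation list stood apart in every alternative run on it. Thinning the deeper library took the histone list to percentile 97.205 and the cell cycle list to 3.87. For named genes, 402 of 462 values stayed within their interval and none of those called changed sign. Depth limits coding genes, of which 50 reached 1000 counts.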

Other observations

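The tests with a bound in the last paragraph were fixed before their values were seen, but after the pattern was noticed, and the genes named in this part were chosen after their values were seen. At the lower minimum of 20 counts, 14 selenoproteins were measured and 12 lay above the coding median, with a relative median of 0.87 (percentile 100). With a trend of ratio on gene length removed, an alternative chosen after seeing the data, it was 0.79. Selenoproteins hold selenocysteine, which is inserted at a recoded UGA codon. The methionine sulfoxide reductase MSRB1 had 43 counts with the reporter and 8 without it (2.29, 1.19 to 3.59), SELENOT had 56 against 18 (1.51, 0.72 to 2.36) and TXNRD3 had 21 against 4 (2.26, 0.69 to 4.26). SELENOW had 21 against 32 (-0.74, -1.61 to 0.10) and TXNRD1 46 against 49. At this minimum the list of heat shock chaperones was also higher, with 20 of 22 above the coding median, and so were the lists of nucleus-encoded oxidative phosphorylation, with 43 of 61 above it, and of histones, with 24 of 32. The histone list was at percentile 99.5, but at 57.8 with the length trend removed. The cell cycle and mitochondrially encoded lists stood apart as lower, with 22 of 34 and 12 of 13 members below the coding median.

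Other RNA classes went different ways. The 69 snoRNA genes had a median of 0.31 (0.25 to 0.42) relative to coding genes, with SNORA2A at 1.47 and SNORD93 at -0.79. The 33 genes of miscellaneous RNA, mostly Y RNAs, were at -0.59 (-0.67 to -0.34), and RNY1 had 51895 counts against 55441. The 43 snRNA genes were at 0.05 (-0.14 to 0.33) and the 54 lncRNA genes at -0.09 (-0.24 to 0.06). Among miRNA genes, MIR340 was at -2.78, with 276 counts against 1730, and MIR200C at 0.85, with 548 against 277. The mitochondrial tRNA gene MT-TE was at 0.74, with 47512 counts against 26044, while the 14 measured genes of its class had a median of -0.20 relative to coding genes.

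Some genes, picked by their values, were nearly absent with the reporter. Genes of mesenchymal and matrix biology among them were TGFBI at 2 counts against 71, SPARC at 5 against 48, FN1 at 6 against 51 and ITGA3 at 1 against 31. Others were MIR211 at 1 against 27, HLA-DRB1 at 1 against 21 and GPM6B at 0 against 17. RNA from another cell type in the library without the reporter is a candidate explanation. The fixed lists of fibroblast, leukocyte, and erythroid and serum markers go with it, at percentiles 2.26, 1.995 and 0.165. They rest on 9, 4 and 2 genes, of which 5, 2 and 2 were lower. The remaining fixed list of other cell types, hepatocyte and keratinocyte markers, was higher with the reporter, at 92 counts against 49 (percentile 94.5). Without CDKN2A, which held most of them, that list had 6 against 15 (percentile 7.26). The members of the fixed lists were planned, but percentiles of their pooled counts were not. Of genes that the line itself expresses, the embryonic kidney and adrenal list was also lower, at -0.71 (-1.23 to -0.20, percentile 6). The neuron-like list was not, at 0.29 (-0.003 to 0.58). However, a further list of 35 mesenchymal genes had a pooled log2 ratio of -0.14 (-0.29 to 0.02). A list of melanocytic genes was at -0.15 (-0.62 to 0.32), and epithelial and MHC class II genes together were at -0.050 (-0.50 to 0.41). Each of these further results met the bound set beforehand against the explanation, but these bounds were poorly chosen. VIM and LAMC1, which this line expresses, held 148 and 146 of the 700 mesenchymal counts, PRAME held 60 of 80 melanocytic counts, and the epithelial and MHC class II lists went apart at 1.24 and -1.02. The question stays open, and selection from many sparse genes may play a part. Among 6296 genes with at least 20 counts, 14 were at least 8-fold lower and 7 at least 8-fold higher with the reporter. By counting intervals, 3 lay wholly beyond 4-fold lower, namely TGFBI, ITGA3 and SPARC, and 2 beyond 4-fold higher. Counting error is thus an unlikely source of those 3, but the intervals do not cover differences between libraries.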
